A study of Mus musculus with 8 samples.

How the data were processed

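Total RNA from palatal shelves, the paired outgrowths of the upper jaw that meet and fuse into the palate, was measured in mouse embryos of embryonic day 14.5. Per the labels, 4 samples carried the genotype R26Pax3/Pax3, 4 were wild type littermates, the strain was a cross of C57BL/6 and SV129, RNA was extracted with Trizol, and biotinylated cRNA was made from 6 µg of total RNA. Samples were grouped by the genotype in their labels and are named here by the replicate numbers given there, which are 1, 3, 4 and 7 for R26Pax3/Pax3 and 2, 6, 8 and 11 for wild type. The labels do not say whether a sample came from 1 embryo or from several, so the p-values measure the spread between these samples.

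The RNA was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, on which several short probes together form a probe set for a transcript. The values used here are linear signal intensities per probe set that the authors made with MAS5, per the submitters' processing notes, which give no version. MAS5 corrects background within each array and scales each array to a common target. In the deposited intensities the mean after leaving out the lowest and highest 2% was 150 on each of the 8 arrays, and the medians lay between 43.5 and 44.9. Such scaling removes differences in overall brightness, and it would hide a change shared by most genes. MAS5 values of dim probe sets are dominated by noise. Detection calls and scanner files were not used here, so a dim signal cannot be told from an absent one.

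The array held 45037 probe sets besides 64 control probe sets, which were left out of all tests. In the annotation of the array, 34945 of the 45037 had a single gene symbol, 932 had several and 9160 had none. Of 18194 Entrez gene identifiers on probe sets with a single symbol, 18032 were found in the RefSeq gene table of assembly GRCm38.p6, and no symbol differed from the one in the annotation. That table was used for names and for the order of genes along chromosomes only, because no genome build is given in the sources used here for the array. No gene was named from a probe set with several symbols, and list members without a probe set of their own were not analysed here.

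Signals were transformed to log2(signal + 16) with no further normalization. Fold changes are therefore on that scale, and they understate the change of dim genes. Probe sets at or below the 40th percentile of the mean over the 8 arrays were left out, which kept 27022 probe sets. Of these, 22766 had a single gene symbol, 594 had several and 3662 had none, and the named ones covered 12329 genes. Genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and with eBayes fitting an intensity trend, and no covariates. The p-values were adjusted by the Benjamini-Hochberg method, and probe sets with an adjusted p under 0.05 were called. Log2 fold changes are R26Pax3/Pax3 minus wild type, with limma's standard error (SE). Signals are given as mean ± SD with n = 4 arrays per group. The number of arrays limits the precision.

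Gene lists were fixed before the data were examined, and 23 of them were tested with camera from limma, two-sided. They cover bone, cartilage, mesenchymal matrix, BMP and Wnt signalling, palate development, neural crest, reported Pax3 targets, muscle, epithelium and other cell types that dissected shelves could hold. The inter-gene correlation was preset at 0.01, each gene was represented by its probe set with the highest mean, and p was adjusted over the lists. Each list was also tested with a correlation estimated from the data, with fry, and, as a test added after the data were seen, by an exact permutation of the array means. With 4 arrays against 4 there are 70 regroupings, and the smallest two-sided exact p is 0.0286. For each list the members past the threshold are counted over all probe sets tested and adjusted over the list alone. A list of 5 sex-linked genes was read as values only.

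The genes named were chosen by a rule written before the data were examined. They are Pax3, the BMP antagonist Sostdc1, the called genes with the largest change whose groups did not overlap, up to 12 per direction without the sex-linked genes, and up to 4 members per list by smallest p. Where fewer than 12 were called in a direction, those were followed by the genes next by unadjusted p, up to 8 in all. Genes named outside this rule are other members of fixed lists or are said to have been chosen after their values were seen.

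The procedure was tested on simulated data for the comparison of R26Pax3/Pax3 with wild type, with 27022 probe sets of which 50 were changed at each of 4 sizes. It recovered 32% of those changed by 0.5 on the log2 scale, 96% at 1 and 100% at 2 and at 3, with 7 false calls in all. These shares do not carry over to the data. The adjusted p of a probe set depends on how many others change, and only 4 were called in the data. Marchf8, with a log2 fold change of -0.91, was not called there (limma adjusted p = 0.124). The simulated errors were also independent between probe sets. In the simulation of the list test, the 1 shifted list was called and 0 unshifted lists were called. That result does not bound the false calls of the list test in the data. There, a split of the arrays other than by genotype gave up to 8 called lists. The correlation within a list was estimated at 0.206 for bone and 0.857 for skeletal muscle structure.

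The alternatives planned were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, eBayes without the trend or with robust settings, array weights, the Xist signal as a covariate for embryo sex, leaving out each array, leaving out probe sets that can match several transcripts, other probe sets of a gene, and other list tests. As a principal component separated the first 4 from the last 4 arrays in order of deposition, that division was added as a covariate after the data were seen, as was the list of reported Pax3 targets without Sostdc1, and differences within each set of 4 are given beside the main values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.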

Results

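Gene expression was measured on 8 arrays, 4 of R26Pax3/Pax3 and 4 of wild type palatal shelves at embryonic day 14.5. R26 stands for Rosa26, a locus on chromosome 6 into which sequences are often inserted for expression. The R26Pax3 allele places Pax3, a paired-box transcription factor of early neural crest and muscle precursors, under its control. The labels name no driver line and do not say which cells of the shelves expressed the allele, so the differences below cannot be assigned to cells. The comparison asks which genes differ in shelves that carry the allele. No pair of arrays held the same values, and the correlation between arrays lay between 0.975 and 0.982. RNA quality did not separate the genotypes. The 3' to 5' ratio of Actb was 1.43 ± 0.0313 in R26Pax3/Pax3 and 1.45 ± 0.0374 in wild type (SD, n = 4 each, exact permutation p = 0.571), and that of Gapdh was 0.757 ± 0.0429 and 0.743 ± 0.0154 (exact permutation p = 0.571). The first principal component, with 21.8% of the variance, did not follow genotype. It lay between -26.6 and -6.25 in the first 4 arrays deposited and between 2.53 and 28.7 in the last 4, and each of these sets held 2 arrays of each genotype.

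Pax3 rose in the R26Pax3/Pax3 shelves. The brightest of its 3 probe sets read 619 ± 88.8 against 162 ± 14.6 in wild type (SD, n = 4 each), a 3.83-fold ratio and a log2 fold change of 1.83 (SE 0.113, limma adjusted p = 1.59e-05). The second read 387 ± 73.1 against 87.0 ± 15.5, a 4.45-fold ratio and a log2 fold change of 1.96 (SE 0.147, limma adjusted p = 0.000106). The wild type shelves thus gave signals of their own on both probe sets, and the lowest mutant array lay above the highest wild type array on each. Within the first and last 4 arrays deposited, the differences were 1.72 and 1.94 for the former and 1.89 and 2.03 for the latter. The third probe set read 82.5 ± 21.5 against 103 ± 14, with a log2 fold change of -0.29 (SE 0.160, limma adjusted p = 1). It may read a part of the transcript that the inserted sequence lacks, and then it checks nothing.

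Few other transcripts differed by genotype. Of 27022 probe sets, 4 passed an adjusted p of 0.05 in limma, 2 higher and 2 lower in R26Pax3/Pax3, and the 2 higher ones were those of Pax3. The lower ones read Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus, and Tia1, an RNA-binding protein of stress granules. At an unadjusted p under 0.05 there were 1314 probe sets, where 1351 were expected by chance, and at 0.001 there were 50, where 27.0 were expected. The 4 arrays of a genotype did not overlap with the other 4 in 2.73% of probe sets, against 2.86% by chance. Without mutant replicate 3 there were 9 calls, and they included the 4.

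Gt(ROSA)26Sor fell to below the median signal of the array. Its probe set read 19.8 ± 7.46 in R26Pax3/Pax3 and 337 ± 53.6 in wild type (SD, n = 4 each), a log2 fold change of -3.31 on the scale with 16 added (SE 0.163, limma adjusted p = 1.84e-06). All 4 mutant values, 12.8 to 30.3, lay below the medians of their arrays and cannot be told from background, so no fold is given and the fall may be larger than this value. The differences were -3.43 within the first and -3.20 within the last 4 arrays. The R26Pax3 allele lies in this locus, so the fall cannot be read as a response to Pax3. An effect of the insertion itself cannot be told apart from one. On 1 probe set of Tia1 the signal fell from 677 ± 85.3 to 71.3 ± 15.2, a 9.49-fold ratio and a log2 fold change of -3.00 (SE 0.136, limma adjusted p = 1.36e-06). The other 5 probe sets of Tia1 did not follow, with log2 fold changes between 0.03 and 0.16, so a lower level of Tia1 as a whole was not measured.

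**Figure D1:**
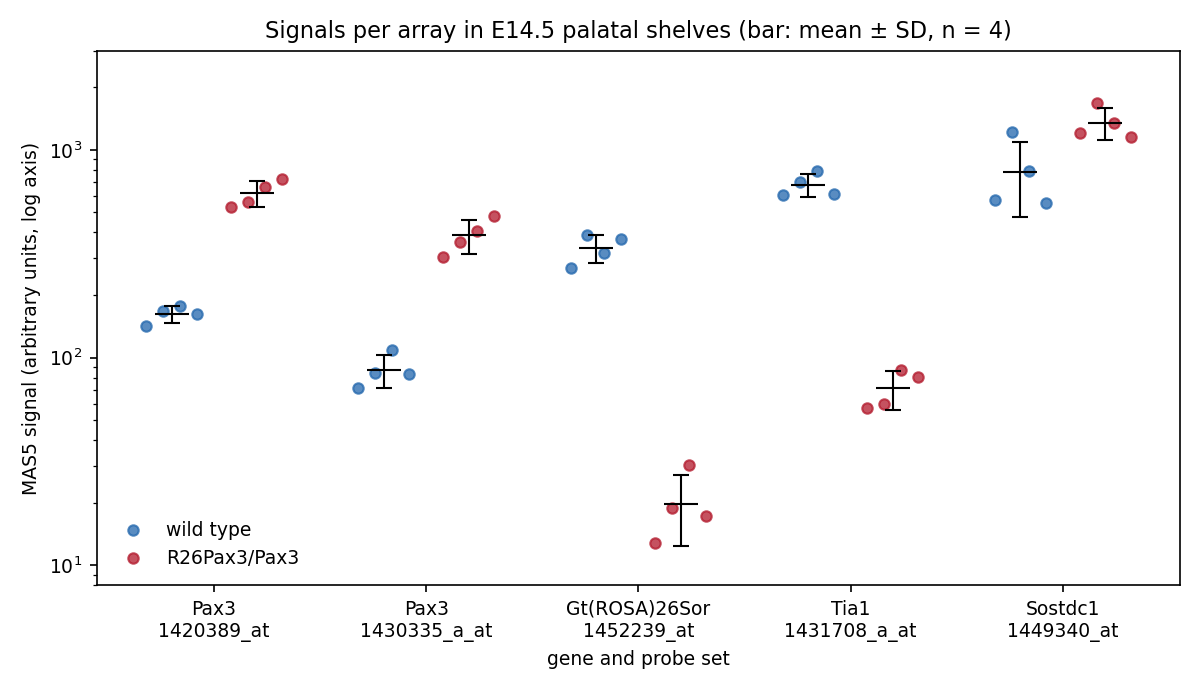
MAS5 signals in arbitrary units on a log axis for 5 probe sets, with a point for each array, wild type in blue and R26Pax3/Pax3 in red, and black bars at the mean ± SD of 4 arrays. The groups are apart for Pax3, Gt(ROSA)26Sor and Tia1, while for Sostdc1 the wild type array at 1217 lies among the mutant arrays.

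Sostdc1, a secreted antagonist of BMP and Wnt signals, had a higher mean in R26Pax3/Pax3 but did not pass the test over all probe sets. Its brighter probe set read 1351 ± 237 against 784 ± 307 (SD, n = 4 each), a 1.72-fold ratio, with a log2 fold change of 0.83 (SE 0.211, limma adjusted p = 0.599). The second probe set read 1088 ± 141 against 670 ± 208, a log2 fold change of 0.73 (SE 0.188, limma adjusted p = 0.599). Wild type replicate 8 read 1217 on the first probe set, above mutant replicates 7 at 1158 and 1 at 1207. Within the first and last 4 arrays the differences were 0.76 and 0.90. Sostdc1 was named beforehand from knowledge of the study's published work, which may rest on these same samples, so its direction is not independent evidence.

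Among BMP genes, the ligand Bmp4 and the antagonist Sostdc1 had higher means, and Bambi, a decoy receptor for BMP and TGF-beta signals, had a lower one. None of the BMP lists shifted as a whole and 0 of their members were called over all probe sets. Of 11 measured BMP antagonists, 6 were higher and 5 lower (camera adjusted p = 0.251), and 1, Sostdc1, passed when adjusted over the list alone (adjusted p = 0.0222). Fst and Bmper, 2 further antagonists, had log2 fold changes of 0.21 and 0.30, and Grem1 had -0.12. Of 12 BMP ligands, receptors and Smads, 6 were higher and 6 lower (camera adjusted p = 0.504), and Bmp4 alone passed when adjusted over the list alone (adjusted p = 0.0252). Bmp4 read 493 ± 52.5 against 376 ± 26.2, a log2 fold change of 0.37 (SE 0.0955). Of 13 measured BMP response genes, 4 were higher and 9 lower (camera adjusted p = 0.203). Bambi read 272 ± 31.6 against 363 ± 24.2, a log2 fold change of -0.40 (SE 0.0994), and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0225). The homeobox genes Msx2, at -0.40, and Msx1, at 0.45, lay on opposite sides without passing.

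Further genes had the smallest p-values and groups that did not overlap, but adjusted p-values of 0.12 or more in limma. On 1 probe set each, all 4 mutant arrays lay above wild type for Gng12, a G protein gamma subunit (346 ± 42.2 against 196 ± 25.2, log2 fold change 0.77), Anxa4, a calcium-dependent phospholipid-binding protein (201 ± 29.4 against 109 ± 14.8, 0.80), and Cdkn2b, an inhibitor of the cell cycle kinases CDK4 and CDK6 (85.9 ± 9.18 against 44.1 ± 4.61, 0.76). The brighter probe set of Gng12 had a log2 fold change of -0.05 (359 ± 19.2 against 372 ± 26.1) and that of Anxa4 had -0.06 (274 ± 29.5 against 287 ± 21.8), so a higher level of either gene as a whole was not measured. All 4 mutant arrays also lay above wild type for Hbegf, a ligand of the EGF receptor (log2 fold change 0.69), Lrrn1, a leucine-rich repeat membrane protein (0.77), Gjb2, which encodes connexin 26 (0.89), and Ier3, an immediate early gene (0.74). Lower in all 4 mutant arrays were Mamdc2 (75.7 ± 11.1 against 142 ± 11.1, log2 fold change -0.79), Marchf8, a membrane-bound ubiquitin ligase (123 ± 19.6 against 246 ± 41.1, -0.91), and Gxylt2, a xylosyltransferase that acts on Notch (268 ± 32.6 against 446 ± 58.0, -0.70). Plod2, a lysyl hydroxylase of collagen, had a log2 fold change of -0.55 on its dimmer probe set and -0.16 on the brighter. Uqcr10, a subunit of respiratory complex III, had -0.60 on 1 probe set without overlap between groups (103 ± 20 against 162 ± 14.7) but -0.01 on the brightest of its 3 probe sets (644 ± 64.2 against 648 ± 48.5). On the dimmest probe set of Uqcr10 (26.6 ± 13 against 76.2 ± 4.69) and for Lrrc46 (23.5 ± 6.70 against 58.4 ± 12.1), all 4 mutant values lay below the medians of their arrays and cannot be told from background, so no size is given.

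Genes of osteoblasts and bone matrix were lower together in R26Pax3/Pax3. Of 16 measured members, 14 were lower and 2 higher, with a mean log2 fold change of -0.29 (camera adjusted p = 4.48e-08). That call was lost with an estimated correlation (adjusted p = 0.166 with an estimated correlation). No member was called over all probe sets, and 6, all lower, passed when adjusted over the list alone. These were Dmp1, a matrix protein of osteocytes (316 ± 104 against 558 ± 219, log2 fold change -0.78), Phex, an endopeptidase of bone cells that governs phosphate balance (-0.70), Ifitm5, an osteoblast membrane protein (753 ± 110 against 1110 ± 198, -0.55), Omd, a proteoglycan of mineralised matrix (-0.54), Col1a1, a chain of type I collagen (-0.33), and Dlx5, a homeobox regulator of osteoblasts (-0.26). The second probe set of Phex, which the filter left out, read 26.5 ± 7.67 against 25.3 ± 16.8. Its values lay below the medians of their arrays and cannot be told from background, so it checks nothing. The abundant matrix genes Ibsp (5229 ± 538 against 5587 ± 847) and Col1a2 had log2 fold changes of -0.09 and -0.13 on their brightest probe sets. Another probe set of Col1a2 had -0.29 without overlap between groups (limma adjusted p = 0.965). The mean over the list was 9.44 ± 0.0937 on the log2 scale in mutant and 9.73 ± 0.144 in wild type arrays, with no overlap (exact permutation p = 0.0286, the smallest that the design allows, and 0.365 after adjustment over the lists). The differences within the first and last 4 arrays were -0.20 and -0.37.

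Matrix genes of mesenchyme and cartilage were also lower on balance. Of 20 measured mesenchymal matrix genes, 18 were lower, with a mean log2 fold change of -0.13 (camera adjusted p = 3.13e-05, and adjusted p = 0.398 with an estimated correlation). None was called over all probe sets, and 2 passed when adjusted over the list alone, Lum, a keratan sulfate proteoglycan (3158 ± 294 against 4030 ± 271, log2 fold change -0.35), and Lox, a collagen cross-linking oxidase (2435 ± 348 against 3180 ± 321, -0.39). The list's difference was -0.0055 within the first and -0.254 within the last 4 arrays, and without mutant replicate 4 it was -0.09 (camera adjusted p = 0.018). Of 15 measured cartilage genes, 11 were lower, with a mean of -0.22 (camera adjusted p = 0.0073, and adjusted p = 0.416 with an estimated correlation). None was called over all probe sets. Adjusted over the list alone, 2 passed, the fibrillar collagens Col11a1 (1563 ± 134 against 2030 ± 126, log2 fold change -0.38) and Col11a2 (167 ± 23.4 against 275 ± 60, -0.66). The differences within the first and last 4 arrays were -0.231 and -0.21, but without wild type replicate 6 the mean was -0.07 (camera adjusted p = 0.368). The call was also lost without mutant replicate 1 (-0.19, adjusted p = 0.0603) or 4 (-0.18, adjusted p = 0.0892), and without mutant replicate 3 the mean was -0.36. Sox9, the regulator of cartilage fate, had a log2 fold change of 0.00 (158.7 ± 19 against 158.3 ± 13.2).

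Genes of epithelium were higher together in R26Pax3/Pax3. Of 21 measured members, 16 were higher and 5 lower, with a mean log2 fold change of 0.23 (camera adjusted p = 5.69e-07). That call was lost with an estimated correlation (adjusted p = 0.185 with an estimated correlation). None was called over all probe sets, and 6, all higher, passed when adjusted over the list alone. These were Krt17 (543 ± 87.0 against 280 ± 88.1, log2 fold change 0.96), Pkp1, a desmosomal plakophilin (570 ± 97.7 against 360 ± 103, 0.67), Krt14, the keratin of basal cells (1279 ± 247 against 827 ± 164, 0.62), Sfn, the 14-3-3 protein of stratified epithelia (0.56), the tight junction gene Cldn6 (0.48) and Pkp3 (0.34). The list members Epcam (0.03), Krt8 (-0.03), Krt18 (-0.06) and Grhl2 (-0.03) had small differences. The array means of the genotypes overlapped (8.80 ± 0.154 against 8.58 ± 0.0960 on the log2 scale, exact permutation p = 0.0857), and the differences within the first and last 4 arrays were 0.22 and 0.233.

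**Figure D2:**
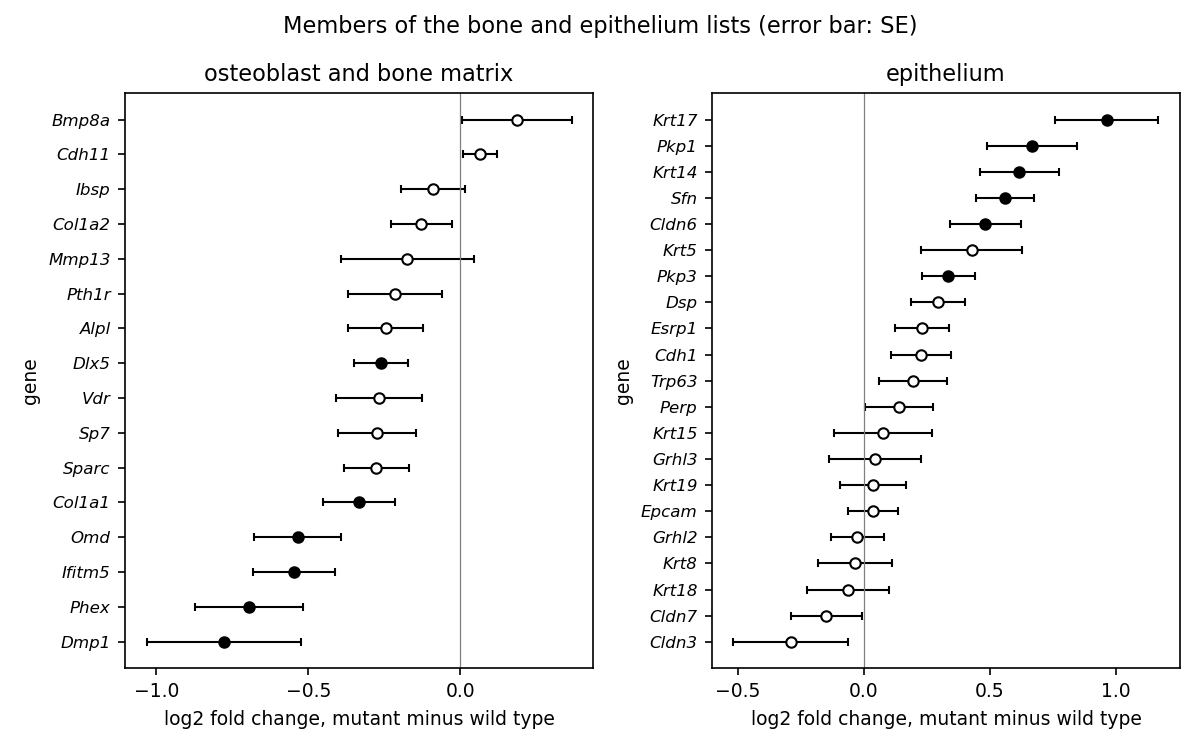
Log2 fold change, R26Pax3/Pax3 minus wild type, of each measured member of the bone and epithelium lists, with bars of 1 SE from limma and filled points for members with p under 0.05 adjusted over the list alone. In the bone list 14 of 16 members lie below 0, and in the epithelium list 16 of 21 lie above it.

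Reported Pax3 target genes were higher on balance, a call that did not hold without the filter on low signals. Of 12 measured members, 8 were higher and 4 lower, with a mean log2 fold change of 0.18 (camera adjusted p = 0.00186, and adjusted p = 0.166 with an estimated correlation). Without the filter the mean was 0.0686 (camera adjusted p = 0.177). The list holds Sostdc1, which is not independent evidence here, and without it 7 of 11 members were higher, with a mean of 0.12 (camera adjusted p = 0.0158, and adjusted p = 0.185 with an estimated correlation). None was called over all probe sets, and 1, Sostdc1, passed when adjusted over the list alone (adjusted p = 0.0242). The receptor tyrosine kinase Ret (43.0 ± 17.2 against 19.3 ± 12.9), the homeobox gene Six4 (0.24) and the growth factor Tgfb2 (0.21) did not pass when adjusted over the list alone (adjusted p = 0.0701 each). All 4 wild type values of Ret lay below the medians of their arrays and cannot be told from background, so no size is given for it. Its value, larger than those of Six4 and Tgfb2, nevertheless enters the means of the list with and without Sostdc1. Those means therefore rest in part on a difference of unknown size, and the mean without Ret was not computed. Met, the receptor of migrating muscle precursors, had a log2 fold change of -0.01, Fgfr4 had -0.05 and Itm2a had -0.03. The differences of the list within the first and last 4 arrays were 0.185 and 0.179, and without mutant replicate 3 the mean was 0.10 (camera adjusted p = 0.0203). Of 15 measured genes of the neural crest and Pax3 network, 8 were higher and 7 lower (camera adjusted p = 0.605), and 0 passed over all probe sets or adjusted over the list alone. Tfap2b, a transcription factor of neural crest, read 238 ± 97.7 against 117 ± 51.5 (log2 fold change 0.94, adjusted p = 0.119 over the list alone).

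Muscle and nerve genes differed between single arrays more than between genotypes. Of 24 measured genes of skeletal muscle structure, 23 were lower in R26Pax3/Pax3, with a mean log2 fold change of -0.53 (camera adjusted p = 1.79e-05, and adjusted p = 0.572 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. Acta1, skeletal muscle actin, ranged from 132 to 1003 among mutant and from 522 to 1168 among wild type arrays. Without mutant replicate 7 the mean of the list was -0.07 (camera adjusted p = 0.431), and without mutant replicate 4 it was -0.82. The differences within the first and last 4 arrays were 0.036 and -1.10. Of 12 measured myogenic regulators, 2 were higher and 10 lower (camera adjusted p = 0.473), none past the threshold over all probe sets or adjusted over the list alone. Of 15 neuronal genes, 14 were higher, with a mean of 0.56 (camera adjusted p = 5.54e-06, and adjusted p = 0.398 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. Tubb3, neuronal tubulin, read 109 ± 37.7 against 64.2 ± 54.8. The differences of the neuronal list within the first and last 4 arrays were 0.0464 and 1.08, and leaving out wild type replicate 11 or 2 gave a mean of 0.36 each, while leaving out wild type replicate 6 gave 0.89. With a pseudocount of 64 the mean was 0.36.

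Of the remaining lists, 2 were called. All 5 measured erythroid genes were higher, with a mean of 0.29 (camera adjusted p = 0.0073, and adjusted p = 0.166 with an estimated correlation), and 0 passed over all probe sets or adjusted over the list alone. Alas2, the first enzyme of heme synthesis in red cells, read 185 ± 28.3 against 134 ± 37.4, and the embryonic globin Hbb-y read 5781 ± 1100 against 4939 ± 337. The list's differences within the first and last 4 arrays were 0.104 and 0.468, without wild type replicate 2 its mean was 0.19 (camera adjusted p = 0.0708), and without the filter on low signals it was 0.13 (camera adjusted p = 0.126). Of 16 immediate early and heat shock genes, 13 were higher, with a mean of 0.15 (camera adjusted p = 0.0326, and adjusted p = 0.303 with an estimated correlation). None passed over all probe sets and 1, Ier3, passed when adjusted over the list alone (adjusted p = 0.00219). This call was also lost without mutant replicate 1 (0.14, adjusted p = 0.0798) or 4 (0.13, adjusted p = 0.13) or wild type replicate 2 (0.15, adjusted p = 0.0899), 6 (0.13, adjusted p = 0.0965) or 11 (0.13, adjusted p = 0.0703), with the filter at the 60th percentile (0.0813, adjusted p = 0.221) and with the mean of all probe sets of a gene (0.15, adjusted p = 0.0529), and with a pseudocount of 64 the mean was 0.0985. The differences within the first and last 4 arrays were 0.176 and 0.134.

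**Figure D3:**
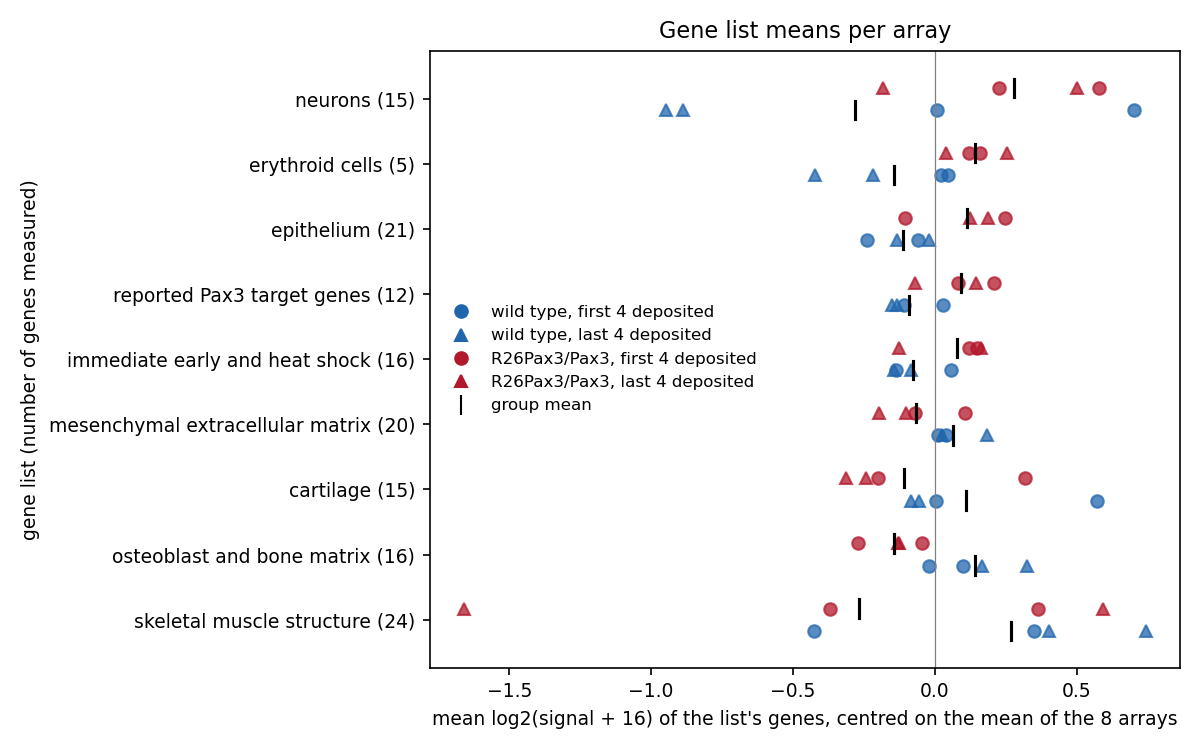
Mean log2(signal + 16) over the genes of each of the 9 lists with a camera adjusted p under 0.05, centred on the mean of the 8 arrays, with a point for each array and a black line at each group mean. Colour shows genotype and shape shows the first or last 4 arrays deposited. The bone list is the only one of the 9 in which the groups do not overlap, and mutant replicate 7 lies lowest for muscle at -1.66.

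The other lists did not pass camera. The 40 measured genes of palate development were split into 22 higher and 18 lower (camera adjusted p = 0.873), with 0 past the threshold over all probe sets or adjusted over the list alone. They included Osr2, a mesenchymal regulator of shelf growth (log2 fold change 0.34), and Snai1, a repressor of epithelial genes (-0.33). Of 24 cell cycle genes, 14 were higher and 10 lower (camera adjusted p = 0.835), with the proliferation marker Mki67 at 1514 ± 30.3 against 1421 ± 117. Of 23 Wnt response genes and antagonists, 13 were higher and 10 lower (camera adjusted p = 0.25), with Wnt11 at a log2 fold change of 0.46 (adjusted p = 0.144 over the list alone). Of 12 tooth germ genes, 7 were higher and 5 lower (camera adjusted p = 0.873). The enamel matrix gene Ambn, at 62.8 ± 16.4 against 112 ± 10.6 (log2 fold change -0.72), was the 1 that passed when adjusted over the list alone (adjusted p = 0.00539). The camera adjusted p was 0.14 for Schwann cells and glia (5 of 7 higher), 0.176 for endothelium (11 of 16 higher), 0.531 for macrophages and leukocytes (10 of 15 higher), 0.845 for hypoxia and glycolysis (8 of 16 higher) and 0.999 for melanocytes (1 of 3 higher). In these 5 lists, as in those of the cell cycle and of Wnt, 0 members passed over all probe sets or adjusted over the list alone, and Ambn did not pass over all probe sets. In all, 9 of 23 lists passed with the preset correlation, 5 higher and 4 lower. None did so with an estimated correlation, none with fry for a shift on balance, and 5 with fry for changes in either direction. These 5 were the lists of bone, epithelium, BMP response genes, and immediate early genes (adjusted p = 0.00708 each) and reported Pax3 targets (adjusted p = 0.0125).

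Genes with small p-values were denser on the chromosome of the Rosa26 locus, a property looked at more closely after the calls were seen. Leaving out Gt(ROSA)26Sor, 7 of 624 measured genes on chromosome 6 (1.12%) had a probe set at an unadjusted limma p under 0.001, against 29 of 11659 genes (0.249%) elsewhere (one-sided Fisher's exact test, p = 0.00194). They were Tia1, Gng12, Anxa4, Gxylt2, Lrrn1, Marchf8 and Kcna5, a potassium channel with a log2 fold change of 0.77 (98.2 ± 13.4 against 52.3 ± 17.7). In the gene order of GRCm38.p6 they lay from 11 to 183 measured genes away from Gt(ROSA)26Sor, on both sides of it. With only the brightest probe set of each gene, the counts were 4 on chromosome 6 and 25 elsewhere (one-sided Fisher's exact test, p = 0.0572).

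**Figure D4:**
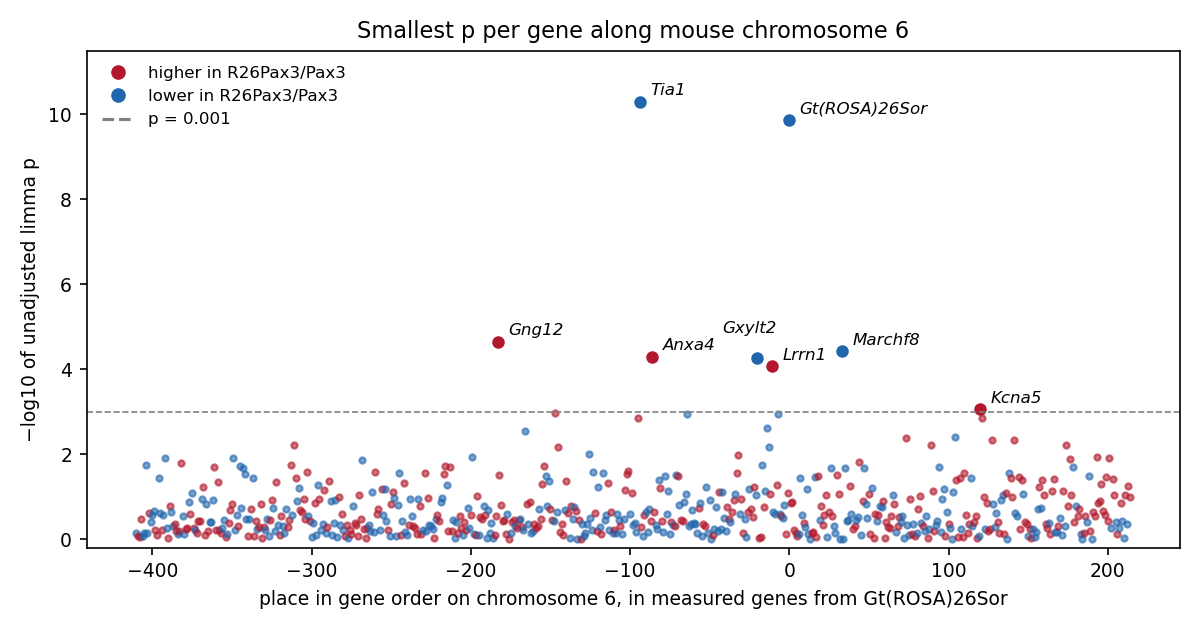
Minus log10 of the smallest unadjusted limma p of each measured gene on chromosome 6 against its place in gene order, counted in measured genes from Gt(ROSA)26Sor, in red where the signal was higher in R26Pax3/Pax3 and in blue where it was lower. The named genes, above the dashed line that marks 0.001, are Gt(ROSA)26Sor and 7 others spread over places from -183 to 120.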

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

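Of the tests in this part, the count of regroupings and the test of a 20 Mb window around the Rosa26 locus were planned, and the other tests were chosen only after the results were seen. Of 254 groups of 4 arrays, 12 held an array far from the other 3, where about 12.7 would do so by chance. Each value below is the gap of that array to its nearest neighbour, divided by the range of the group, on the log2 scale. Wild type replicate 8 lay low for the third probe set of Pax3 (0.884). Mutant replicate 1 lay low for Plod2 (0.852) and high for the Wnt antagonist Dkk2 (0.929). Mutant replicate 3 lay low for Uqcr10 (0.958) and for Ifitm5 (0.929). Wild type replicate 11 lay high for Bambi (0.871). Wild type replicate 6 lay high for the cartilage proteoglycan Acan (0.837) and for the mean of the cartilage list (0.867). Wild type replicate 8 lay high for the mean of the neural crest list (0.8291). Wild type replicate 2 lay high for the mean of the mesenchymal matrix list (0.84) and low for that of the hypoxia list (0.874). Mutant replicate 7 lay low for the mean of the immediate early list (0.848).

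The number of called probe sets was 4, and 2 of the 35 splits of the arrays into 4 and 4 gave as many, a share that does not by itself exclude chance for the count. The other of these 2, and the highest, gave 39, and it was the split of the first from the last 4 arrays deposited, which points to a structure of the samples other than genotype. The remaining splits gave at most 2. With the division by deposition as a covariate, the same 4 probe sets were called, each with an adjusted p of 0.000106 or less in the comparison without it. For the gene lists, 1 of the 35 splits gave as many as the 9 called, the real one, and the highest other gave 8. The margin is 1 list, as 4 other splits gave 8, and 0 lists passed in limma with an estimated correlation, with fry for a shift on balance or with the adjusted exact permutation of array means, which 1, bone, passed before adjustment. The count is therefore weak evidence against chance and says nothing of any single list.

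Genes with the smallest p-values were denser on chromosome 6, where in the planned test 1 of 177 measured genes within 20 Mb of Gt(ROSA)26Sor was called against 2 elsewhere (one-sided Fisher's exact test, p = 0.0426), but that gene was Gt(ROSA)26Sor itself, so the test leaves the matter open. Without it, 7 of 624 genes on chromosome 6 against 29 of 11659 elsewhere had an unadjusted p under 0.001 (Fisher's exact test, p = 0.00194), a test redone with any probe set of a gene after the brightest alone had given p = 0.0572 and left out Tia1, Gng12 and Anxa4. An effect confined to adjacent genes is argued against as the whole cause, since only 2 of the 7 lay among the 20 measured genes on either side of the locus. It stays open for those 2, because these 40 neighbours are a small part of the 624 genes. Among the other neighbours, the groups also did not overlap for Cntn4 (log2 fold change -0.91), Edem1 (-0.48), Trnt1 (-0.33), Vhl (-0.23) and Arpc4 (-0.20). All of these were lower in R26Pax3/Pax3, and none had an unadjusted p under 0.001. Whether changed genes were denser near the locus than on the rest of chromosome 6 was not tested, so a part played by such an effect stays open. DNA of the other parental strain, carried along with the allele in this strain cross, could account for the spread along the chromosome, and a variant in the sequence that a single probe set reads could account for Tia1, Gng12 and Anxa4, of whose other 8 probe sets 0 differed in the same direction by at least 50% as much, against 9 of 17 for genes on other chromosomes, although another probe set of Anxa4 had 0.30 (SE 0.176). These are hypotheses, and an effect of Pax3 on these genes stays open and was not tested. The 8 probe sets come from 3 genes, most of them from Tia1, and the 17 come from 10 genes, so they are not independent. Those 3 genes are also the ones whose brightest probe set had missed the cut, so part of the disagreement follows from how they were found.

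Bone genes were lower and epithelial genes higher, as a change in the make-up of the dissected tissue might bring about. Less adjoining muscle and cartilage is argued against for the bone genes, since their difference was -0.342 with both as covariates and -0.285 without (permutation p = 0.00548 over the 40320 orders of the residuals, an approximate test not bound by the 70 regroupings, and permutation p = 0.0286 over those 70). These covariates do not measure how much bone a sample held, so the fit does not speak to the amount of bone dissected. A smaller share of mesenchyme stays open for them because, although their shift minus that of palate development was -0.301 (exact permutation p = 0.0286), that list went both ways, 18 of 20 mesenchymal matrix genes and 17 of 18 collagen-modifying genes were lower, and the shift minus that of mesenchymal matrix was -0.156 (exact permutation p = 0.2). For the epithelial genes the share of mesenchyme cannot be told apart from a difference within epithelium, because their shift exceeded that of endothelium and leukocytes by 0.182 with overlapping arrays (exact permutation p = 0.0571). The list members Epcam, Krt8, Krt18 and Grhl2 had small differences, so the rise was not even over the list. They are a few of 21 measured members, of which 16 were higher, so they do not tell these explanations apart. Lower expression in bone cells or less bone, with genotype as the biological explanation in the design, also stays open. It was not told apart from a difference in the amount of bone dissected.

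Muscle genes were lower and neuronal genes higher, with wide differences among arrays of the same genotype. For muscle the difference between genotypes was -0.534, while arrays of the same genotype lay up to 2.25 apart (exact permutation p = 0.457). For neurons it was 0.561, with up to 1.65 between arrays of the same genotype (exact permutation p = 0.257). Dissection differences between single samples could therefore account for both, and an effect of genotype was not excluded.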

How the results depend on the processing

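The division by order of deposition, the permutation of array means and the list of Pax3 targets without Sostdc1 were chosen after seeing the data, and the others were set beforehand. No paired analysis was run, because the groups compared share no replicate numbers and the sample titles name no litter. Any differences between litters are therefore not modelled in the p-values. Every alternative was run, but for the one that left out probe sets whose names end in _x_at, _s_at or _a_at only the counts of calls were recomputed. The 4 called probe sets were called in every alternative but that one, where 2 were called, 1 higher and 1 lower, because the other 2 were among those left out. Leaving out 1 array gave 4 to 9 calls, 2 to 5 higher and 2 to 4 lower. Of 2002 alternatives for 100 named results, 1961 kept their direction and side of the threshold, 5 passed it (Gxylt2 with Xist as a covariate, Lrrn1 and Ier3 without mutant replicate 3, and Gjb2 and Marchf8 without wild type replicate 2) and 36 reversed. Outside the called probe sets the adjusted p was 0.12 or more in the main setting, and the alternatives reuse the same arrays. Keeping the side of the threshold therefore says little about the uncalled genes. Some of the 36 reversals came from dim probe sets that the filter had left out, whose signs cannot be told from noise. Of 322 alternatives for the 14 lists that did not pass, 287 stayed, 3 passed and 32 reversed. Those that passed were leukocytes without mutant replicate 3 (0.13), endothelium without mutant replicate 7 (0.09) and Schwann cells without wild type replicate 6 (0.19). Signals near background limit the dim genes. The cause was not tested for any change below.

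The count of called lists was 9 in the main setting, 7 to 10 over the other settings with the preset correlation, and 0 with an estimated correlation, with fry for a shift on balance and with the exact permutation of array means. Under these 3 tests the mean log2 fold changes are as before, at -0.29 for bone, 0.18 for reported Pax3 targets, -0.53 for muscle, 0.23 for epithelium, -0.22 for cartilage, 0.29 for erythroid cells, 0.56 for neurons, -0.13 for mesenchymal matrix and 0.15 for immediate early genes. Over all alternatives the adjusted p ranged from 3.17e-10 to 0.365 for bone, 0.00031 to 0.365 for Pax3 targets, 7.8e-13 to 0.701 for muscle, 1.26e-10 to 0.365 for epithelium, 3.41e-05 to 0.673 for cartilage, 0.00182 to 0.365 for erythroid cells, 2.56e-14 to 0.591 for neurons, 5.05e-07 to 0.426 for mesenchymal matrix and 0.00375 to 0.365 for immediate early genes. Calls were also lost without a filter for reported Pax3 targets (0.0686) and erythroid cells (0.13), and for immediate early genes with the filter at the 60th percentile (0.0813) and with the mean of all probe sets of a gene (0.15). A pseudocount of 64, which by its construction shrinks differences of dim genes, kept both calls but lowered the mean to 0.36 for neurons and 0.0985 for immediate early genes. Leaving out 1 array gave -0.36 to -0.0658 for cartilage, 0.13 to 0.22 for immediate early genes, -0.82 to -0.0705 for muscle and 0.19 to 0.35 for erythroid cells.

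Lists near 0 reversed in some settings. The cell cycle list gave 0.00221 with median centring, 0.000479 with a pseudocount of 64, 0.000686 at the 60th percentile, 0.00269 with array weights and 0.0104 with Xist as a covariate. Melanocytes gave 0.0562 with a pseudocount of 1 and 0.0455 at the 60th percentile, where tooth germ gave -0.0809. BMP ligands gave -0.0386 without a filter and -0.00385 with array weights. Hypoxia gave -0.000787 with array weights and -0.00302 with Xist, and leukocytes gave -1.09e-05 with Xist. Leaving out 1 array gave -0.0488 to 0.13 for leukocytes, -0.0651 to 0.11 for melanocytes, -0.0202 to 0.022 for the cell cycle, -0.024 to 0.039 for hypoxia, -0.0192 to 0.0425 for BMP ligands, -0.0143 to 0.0408 for palate development and -0.0754 to 0.17 for tooth germ. Among named genes it gave -0.0208 to 0.27 for Cnp, -0.0184 to 0.0837 for Erbb3, -0.33 to 0.0662 for Slc45a2 and -0.17 to 0.00206 for Kit. Other probe sets of a gene that the filter kept reversed for Pax3 (-0.29), Gng12 (-0.0477), Anxa4 (-0.0641), Tia1 (0.0941, 0.0352, 0.0325, 0.11 and 0.16), Smad4 (-0.0232), Sfrp1 (0.0381 and 0.00145), Isl1 (-0.0375), Mbp (-0.0874), Cnp (-0.22 and -0.0442), Fgf9 (-0.00842) and Kif11 (0.014). Dim probe sets that the filter had left out reversed for Phex (0.12), Msx2 (0.0383), Osr2 (-0.0472), Ret (-0.14), Slc4a1 (-0.17), Ptprc (0.0537), Mbp (-0.21 and -0.22), Erbb3 (-0.0673), Mitf (-0.23), Slc45a2 (0.20) and Sp6 (-0.0233 and -0.15). The signs of these dim probe sets cannot be told from noise, so they do not speak against the brighter ones.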

Other observations

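All tests in this part were chosen after the results were seen. Genes of enzymes that modify collagen were looked at because Plod2 and P4ha2, a prolyl hydroxylase of collagen, were lower. Leaving out these 2 genes, 17 of 18 measured members were lower and 1 higher, with a median log2 fold change of -0.16. Adjusted together with the 23 fixed lists, the list passed camera (adjusted p = 4.22e-06), and that call was lost with an estimated correlation (adjusted p = 0.275 with an estimated correlation). The array means of the genotypes overlapped (exact permutation p = 0.0857). P4ha1, another prolyl hydroxylase, read 565 ± 13.8 against 755 ± 105 and was the 1 member that passed when adjusted over the list alone, and none passed over all probe sets. Genes of the outer epithelial layers were looked at because Krt6a, Lgals7 and Gjb2 were higher. Leaving out these 3, 8 of 12 measured members were higher and 4 lower, with a median of 0.0556 (camera adjusted p = 0.0834, adjusted p = 0.354 with an estimated correlation, and exact permutation p = 0.286), and 0 passed over all probe sets or adjusted over the list alone.

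Signals of sex-linked genes differed between arrays within each genotype. Xist, the transcript of the inactive X chromosome, was high in mutant replicates 3 and 4 and in wild type replicates 2, 6 and 8. Genes of the Y chromosome such as Eif2s3y were high in mutant replicates 1 and 7 and in wild type replicate 11, where Eif2s3y read 333, 364 and 410.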
